A study of Mus musculus with 8 samples.

How the data were processed

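The deposited table held raw counts for 24419 genes in 16 columns, a maternal and a paternal column for each of the 8 libraries, per the labels of its header and the whole-number values. Per the submitters' notes, RNA was amplified with SMART-Seq v4 and libraries were made with Nextera XT from 200 pg of cDNA, reads were extracted with bcl2fastq 2.17, trimmed with fastp 0.21.0 and aligned with STAR 2.7.6a to mm10. How reads were assigned to alleles and how genes were counted is not given in the sources used here. The kit does not keep strand, so that overlapping antisense genes such as Xist and Tsix cannot be told apart. Reads carry no molecular barcodes, so that counting intervals and floors cover counting error only. Gene symbols were matched to RefSeq and GENCODE annotations of the same mouse build, which located all but 122 genes. Every column was matched to a sample (0 columns without one).

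The planned tests had assumed counts not divided by allele, and they were run on the sum of the maternal and paternal counts. Tests of maternal counts, of paternal counts and of the allelic ratio were added after the file was seen. The sum includes only reads that cover a variant. Genes were kept by filterByExpr of edgeR (9224 genes for sums, 8090 for maternal and 7711 for paternal counts), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 8 libraries with 1 mean per group and 4 residual degrees of freedom. Contrasts were Eed matKO against Eed CTR, Eed/Xist matDKO against Eed/Xist CTR, the second effect minus the first, and Eed/Xist CTR against Eed CTR. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.0408 for sums, 0.0708 for maternal and 0.0765 for paternal counts.

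The allelic ratio was tested in edgeR on all 16 columns, with a term per library and a term per group and allele, for 8631 genes with a mean of 10 counts or more. Each allele's columns were scaled by TMM on autosomal genes, so that allelic changes are relative to the autosomes. Maternal shares are means of the per-library percentages, with the standard deviation over the 2 libraries. CPM values are relative to all allele-assigned counts of a library.

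Gene lists were written from general knowledge before the counts were read. They cover X-linked, X-escape, X-inactivation centre, imprinted X cluster and Y-linked genes, noncanonical and canonical imprinted genes, PRC2, PRC1, modifiers of H3K27 and H3K9, DNA methylation, developmental regulators, trophectoderm, inner cell mass, primitive endoderm, FGF-ERK, p53 targets, integrated stress response, glycolysis, oxidative phosphorylation, ribosomal proteins, cell cycle, zygotic genome activation, oocyte, cumulus and sperm genes. The X-linked list left out Xist. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over 96 tests of list and contrast (88 for paternal counts). Genes adjusted over the list alone were counted beside those adjusted over all genes.

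Named genes were Eed and Xist, the 10 called genes with the largest rise and the 10 with the largest fall in each knockout (5 each way for the difference and for the controls), and the 4 tested members of each list with the smallest p (all members of the noncanonical core list). The genes with the largest changes needed an average log2 CPM of 3 or more, no overlap between the library values of the groups compared (not asked for in the difference) and a symbol other than a provisional Gm or Rik one. Genes of the allelic tests and other genes of the X chromosome and the X-inactivation centre were named after the results were seen. For a group with 0 counts, the fold is a bound from 3 counts over the group. For 1 to 3 counts, a count ratio is given with its exact 95% interval.

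The procedure was run on counts drawn from a negative binomial distribution at the common dispersion, in which 200 genes per knockout had been changed. For Eed matKO it recovered 51.6% of 1.5-fold, 64.2% of 2-fold and 98.4% of 4-fold changes in summed counts, and 8 of the unchanged genes were called among 9071 tested. For allelic ratios it recovered 8.96%, 32.3% and 75.8%. A shift of -0.5 planted in maternal X-linked counts came back as -0.49.

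Alternatives were size factors of DESeq2, TMM on autosomes, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 10 CPM, a fit to 1 set alone, a replicate block, stricter thresholds (adjusted p under 0.01, or an absolute log2 fold change of 1 or more) and leaving out each library in turn. Y-linked expression as a covariate was planned but not run, because all 48 Y-linked genes had 0 counts.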

Results

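Messenger RNA was sequenced from mouse morulae that differed in whether the egg had carried Eed and Xist. EED is a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3, and Xist is the long noncoding RNA that coats an X chromosome and starts its silencing. Mothers with floxed Eed, or floxed Eed and Xist, either carried the oocyte-specific Zp3-Cre recombinase or did not, and all eggs were inseminated in vitro with sperm of the PWK/PhJ strain. The resulting embryos are called Eed matKO, Eed/Xist matDKO and, without Cre, Eed CTR and Eed/Xist CTR. PWK/PhJ differs in sequence from the mothers' background, so that reads over variants were divided into maternal and paternal counts. Each of the 4 groups had 2 libraries, made at 79 hours after insemination from 5 pooled embryos per library in the Eed set and 13 in the Eed/Xist set. Allele-assigned counts ranged from 961098 to 1138965 per library, between 12196 and 13083 genes had at least 1 count, and the 10 highest genes together took 1.12% to 1.24% of the counts. Nothing says that the libraries of a group came from separate inseminations or mothers, so that p-values measure only the spread between these pools.

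The targeted genes were examined first. Eed (chromosome 7, 89954654 to 89980976, mm10) kept an intact paternal allele in every embryo. The maternal share of Eed counts was 43.5% ± 3.1 (SD, n = 2) in Eed CTR and 27.8% ± 4.0 (SD, n = 2) in Eed matKO, and it was 42.1% ± 4.1 (SD, n = 2) in Eed/Xist CTR and 23.3% ± 3.1 (SD, n = 2) in Eed/Xist matDKO. Maternal Eed counts were lower in Eed matKO with a log2 fold change of -0.96 (SE 0.21, edgeR adjusted p = 0.012), and in Eed/Xist matDKO the value was -0.92 (SE 0.21, adjusted p = 0.081). The sum of both Eed alleles had log2 fold changes of -0.21 (SE 0.13, adjusted p = 0.34) and -0.13 (SE 0.12, adjusted p = 0.80). Which part of each gene was deleted is not given in the labels, so that transcripts of a deleted allele can still give reads.

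Xist (X chromosome, 103460373 to 103483233, mm10) rose in Eed matKO, and the rise came from the maternal allele. Its summed counts went from 568 CPM (counts per 1e6 counts) ± 93.1 (SD, n = 2) to 921 CPM ± 79.6 (SD, n = 2), a log2 fold change of 0.71 (SE 0.14, edgeR adjusted p = 0.0085). Maternal Xist counts rose by 1.66 on the log2 scale (SE 0.14, adjusted p = 1.7e-06), while paternal Xist counts had a log2 fold change of -0.06 (SE 0.26, adjusted p = 0.95). In Eed/Xist matDKO, maternal Xist counts had a log2 fold change of -0.25 (SE 0.14, adjusted p = 0.72) and summed counts one of -0.04 (SE 0.14, adjusted p = 0.98). The maternal effect differed between the knockouts by -1.91 on the log2 scale (SE 0.20, adjusted p = 6.1e-05). The control groups differed as well, with 203 and 144 maternal Xist counts in Eed CTR and 333 and 341 in Eed/Xist CTR. This gap between the controls is part of the -1.91. Antisense Tsix rose in Eed/Xist matDKO from 17.5 CPM ± 3.1 (SD, n = 2) to 117 CPM ± 3.6 (SD, n = 2), a log2 fold change of 2.74 (SE 0.20, adjusted p = 3.8e-05), and 96.4% ± 5.1 (SD, n = 2) of its counts there were maternal. The library kit does not mark strand, so that reads from Xist and Tsix where they overlap cannot be told apart. The rise of summed Xist counts missed the threshold without Eed CTR replicate 2 (log2 fold change 0.55, adjusted p = 0.077) and without Eed matKO replicate 1 (0.63, adjusted p = 0.052).

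The main comparison asked what the loss of maternal EED changes in the morula. In Eed matKO, 87 of 289 X-linked genes fell in maternal counts and 35 of 183 rose in paternal counts. Of the noncanonical imprinted genes, 4 of 6 core and 6 of 14 preimplantation members rose in maternal counts, and 11 of 23 trophectoderm genes fell in summed counts. None of these lists passed camera with an estimated correlation. Of 9224 genes tested on the sum of both alleles, 393 rose and 458 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 67 of these 851 genes were X-linked. Lincenc1, a long noncoding RNA of pluripotent cells, rose from 4.88 CPM ± 5.5 (SD, n = 2) to 296 CPM ± 75.0 (SD, n = 2). Its log2 fold change was 5.89 (SE 0.48, adjusted p = 4.9e-05), and 99.9% ± 0.20 (SD, n = 2) of its counts in Eed matKO were maternal. Dynap (45 counts against 1 in the controls), Dcc, the netrin receptor (24 against 1), and Ddx60 (28 against 3) also rose, with count ratios of 46.2 (95% exact interval 7.89 to 1866), 24.7 (4.02 to 1014) and 9.59 (2.96 to 49.3). Xdh, xanthine dehydrogenase, had no count in Eed CTR and was at least 6.85-fold higher, against 3 counts over the group. Ciita, Zfhx4, Kng2, Cd300ld and Ptpn22 rose by 2.74 to 3.33 on the log2 scale, with adjusted p between 0.00078 and 0.028. Kng2 has a close relative in Kng1, with which it can share reads.

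X-linked genes were among those that fell most in Eed matKO. Msn, which encodes the membrane-cytoskeleton linker moesin, fell from 81.4 CPM ± 6.1 (SD, n = 2) to 7.11 CPM ± 0.25 (SD, n = 2), a log2 fold change of -3.48 (SE 0.31, edgeR adjusted p = 7.3e-05). Mbnl3, an RNA-binding protein gene, had a log2 fold change of -3.49 (SE 0.59, adjusted p = 0.0040). Rnf128, Plac1 and Dmd, also X-linked, had 2, 2 and 1 counts left in Eed matKO against 73, 49 and 24 in its controls. The autosomal Grik3, Fam19a5 and St6galnac4 had 2, 3 and 2 counts against 34, 37 and 24. Gulp1 had no count in Eed matKO and was at least 4.87-fold lower, against 3 counts over the group. Rian, a maternally expressed RNA of the Dlk1-Dio3 region, had 1 count against 43, a ratio of 41.8 (95% exact interval 7.12 to 1691). Most changes of the 851 genes were moderate, with a median absolute log2 fold change of 0.74.

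Part of the X-linked genes were lower on the maternal allele in Eed matKO. Of 289 X-linked genes measured on maternal counts, 87 fell, 3 rose and 199 did not pass the test, and adjusted over the list alone 126 fell and 6 rose. Their median log2 fold change was -0.56 (camera, preset correlation, adjusted p = 3.4e-22; adjusted p = 0.081 with an estimated correlation; fry adjusted p = 0.0053), while the autosomal medians ran from -0.06 to 0.05. The X share of maternal counts was 3.92% ± 0.15 (SD, n = 2) in Eed CTR and 2.83% ± 0.11 (SD, n = 2) in Eed matKO. Hmgn5, a nucleosome-binding protein gene, fell in maternal counts by 2.54 on the log2 scale (adjusted p = 4.6e-07), and its summed counts fell from 161 CPM ± 6.6 (SD, n = 2) to 44.1 CPM ± 3.5 (SD, n = 2). Rlim, the E3 ubiquitin ligase that acts on Xist regulation, fell in summed counts from 165 CPM ± 7.2 (SD, n = 2) to 54.8 CPM ± 3.4 (SD, n = 2), with a log2 fold change of -1.58 (SE 0.12, adjusted p = 4.9e-05). The X-linked noncoding RNA C430049B03Rik fell by 2.40 (SE 0.23, adjusted p = 0.00012). In the X-inactivation centre, Jpx rose (2.46, SE 0.62, adjusted p = 0.030) and Tsx fell (-1.44, SE 0.36, adjusted p = 0.029). That list's median was -0.13 on summed counts, with 2 of 7 members higher and 2 lower (2 and 2 adjusted over the list alone).

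**Figure D1:**
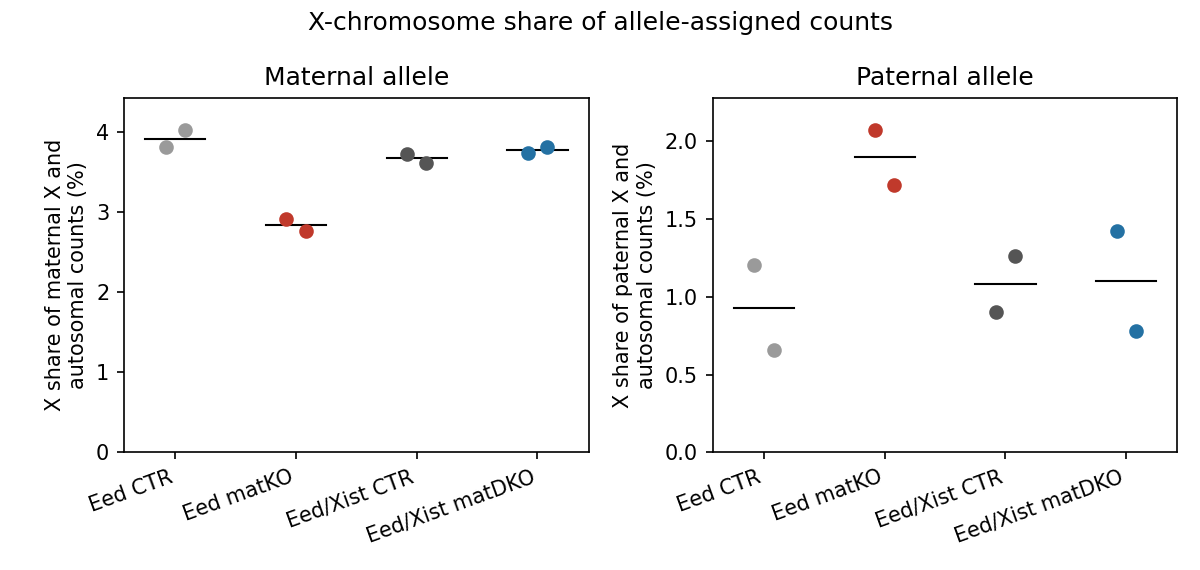
X-chromosome share of the maternal counts (left) and of the paternal counts (right), in percent of each allele's X-linked and autosomal counts. Each point is 1 library and each line the mean of a group's 2 libraries; Eed matKO averages 2.83% on the maternal side and 1.90% on the paternal side, against 3.92% and 0.930% in Eed CTR.

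Part of the paternal X-linked genes were higher in Eed matKO. Of 183 measured on paternal counts, 35 rose, none fell and 148 did not pass the test in edgeR (83 rose and none fell adjusted over the list alone). The median log2 fold change was 1.09 (camera, preset correlation, adjusted p = 1.8e-25; adjusted p = 0.466 with an estimated correlation of 0.51; fry adjusted p = 0.24), and the highest autosomal median was 0.04. The paternal X share was 0.930% ± 0.39 (SD, n = 2) in Eed CTR and 1.90% ± 0.25 (SD, n = 2) in Eed matKO. Eif2s3x and Ddx3x, which escape X inactivation, rose in paternal counts, with adjusted p of 0.030 and 0.031 and a log2 fold change of 1.58 for Ddx3x. Over both alleles together the X-linked median was -0.06 (306 genes, 51 lower, 15 higher and 240 not past the test; camera adjusted p = 0.085). Without Eed CTR replicate 1 the paternal median was 1.69, and without Eed CTR replicate 2 it was 0.75. The median over both alleles was -0.26 without Eed matKO replicate 1 (adjusted p = 0.00098) and -0.11 without Eed CTR replicate 2 (adjusted p = 0.029).

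**Figure D2:**
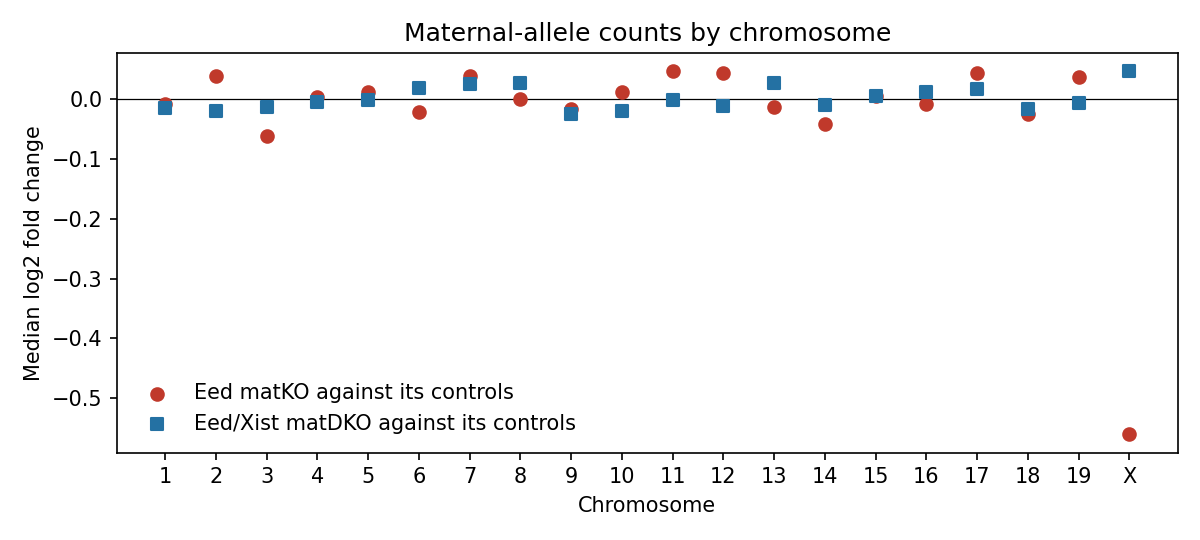
Median log2 fold change of maternal-allele counts for the genes of each chromosome (1 to 19 and X). Circles compare Eed matKO and squares Eed/Xist matDKO with their own controls; the X chromosome lies at -0.56 in Eed matKO and at 0.05 in Eed/Xist matDKO.

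Part of the noncanonical imprinted genes, whose maternal copy is silenced by H3K27 trimethylation inherited from the oocyte, gained maternal expression in Eed matKO. Over the 6 members of the extraembryonic core list, the maternal share of counts was 22.8% ± 0.42 (SD, n = 2) in Eed CTR and 52.8% ± 4.2 (SD, n = 2) in Eed matKO. Maternal counts of the list were 202 and 218 in Eed CTR and 633 and 501 in Eed matKO. Paternal counts were 695 and 725 against 502 and 505, so that fewer paternal counts also raised the share. The median log2 fold change of paternal counts was -0.40 in this list and -0.35 in the preimplantation list. Maternal counts of 4 of the 6 rose and none fell in edgeR (6 rose adjusted over the list alone), with a median log2 fold change of 1.44 (camera adjusted p = 1.3e-06; adjusted p = 0.081 with an estimated correlation; fry adjusted p = 0.0030). The maternal share of Sfmbt2, a Polycomb-group gene required in the placenta, was 1.096% ± 0.79 (SD, n = 2) in Eed CTR and 49.9% ± 7.6 (SD, n = 2) in Eed matKO (log2 allelic change 6.15, SE 0.45, adjusted p = 6.8e-09). Of the counts of Gab1, a signalling adaptor gene, 206 of 764 were maternal in Eed CTR and 549 of 1004 in Eed matKO (1.43, SE 0.18, adjusted p = 4.4e-05). Slc38a4, an amino acid transporter gene, had 0 of 160 maternal counts in Eed CTR, which allows a share of up to 1.88%, and 16.2% ± 2.4 (SD, n = 2) in Eed matKO (adjusted p = 0.0092). Maternal counts of Jade1 rose by 0.55 on the log2 scale (adjusted p = 0.031), while those of Smoc1 (1.54, adjusted p = 0.086) and Platr20 (1.19, adjusted p = 0.096) did not pass the test. Of 14 members of the wider preimplantation list, maternal counts of 6 rose and none fell (8 rose adjusted over the list alone; median 1.27, camera adjusted p = 1.0e-07; adjusted p = 0.081 with an estimated correlation). Not every member had a silenced maternal copy here. In the 2 Eed CTR libraries Platr4 was 91.5% and 98.2% maternal and Etv6 90% and 100%, so that a maternal rise there is no gain from a silenced copy. The core gene Jade1 was 42.8% and 41.15% maternal in these libraries, so that its maternal copy was not silenced either. In the Eed matKO libraries Jade1 had 61.5% and 59.3%. The 10 members of both lists that rose became 6 without Eed CTR replicate 1, without Eed CTR replicate 2 or without Eed matKO replicate 1. In the preimplantation list the maternal share of Bbx was 8.82% ± 3.2 (SD, n = 2) in Eed CTR and 45.4% ± 3.9 (SD, n = 2) in Eed matKO, and that of Fam198b was 23.0% ± 0.58 (SD, n = 2) and 50.1% ± 2.5 (SD, n = 2). The autosomal maternal share as a whole was 52.2% ± 0.16 (SD, n = 2) in Eed CTR and 57.0% ± 2.8 (SD, n = 2) in Eed matKO, a median allelic shift of 0.27 on the log2 scale, and Eed matKO replicate 2 alone had 54.98%. In Eed/Xist matDKO the median shift was -0.14, and these shifts were removed before allelic ratios were tested.

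**Figure D3:**
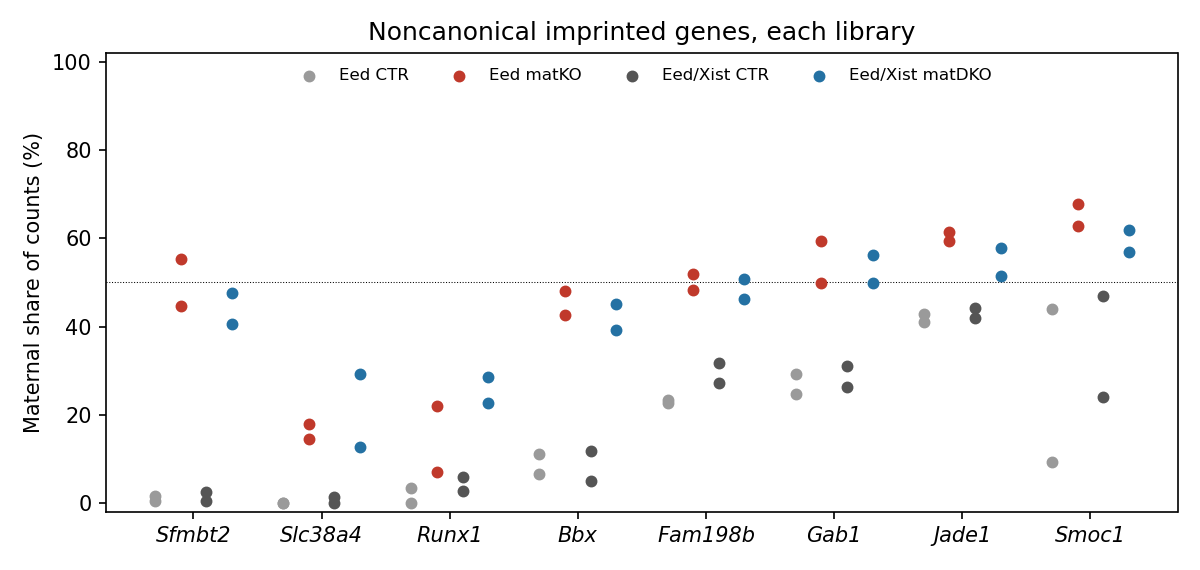
Maternal share of allele-assigned counts, in percent, for 8 noncanonical imprinted genes picked from the 2 lists. Each point is 1 library and the groups have separate colours. The dotted line marks equal expression of both alleles. Other members with counts are not drawn, such as Platr4 and Etv6, which were mostly maternal in every group. Sox21, also not drawn, had 33.3% and 45.5% in Eed CTR and 40.5% and 40% in Eed matKO. Sfmbt2 averages 49.9% in Eed matKO and 44.1% in Eed/Xist matDKO, against 1.096% and 1.54% in their controls.

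On summed counts fewer of these genes passed the test. In the core list only Gab1 rose (log2 fold change 0.45, SE 0.06, edgeR adjusted p = 0.0018) and 5 of 6 members did not pass the test (2 rose adjusted over the list alone; median 0.22). In the preimplantation list Bbx, Platr4 and Etv6 rose by 0.65 (adjusted p = 0.015), 1.14 (adjusted p = 0.0026) and 1.36 (adjusted p = 0.048), and 15 of 18 members did not pass (5 rose and 3 fell adjusted over the list alone; median 0.27). Platr4 and Etv6 were nearly all maternal in Eed CTR already, with 119 of 126 and 17 of 18 counts. Of 19 canonical imprinted genes, whose marks are DNA methylation, Rian and Meg3 fell and 17 did not pass the test (2 fell adjusted over the list alone). Meg3, from the same region as Rian, went from 41.4 CPM ± 7.5 (SD, n = 2) to 5.10 CPM ± 1.6 (SD, n = 2), with a log2 fold change of -2.99 (SE 0.44, adjusted p = 0.0019).

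Part of the trophectoderm genes, which mark the lineage that forms the placenta, were lower in Eed matKO. Of 23 measured, 11 fell, none rose and 12 did not pass the test (13 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -0.31 (camera adjusted p = 0.0016; adjusted p = 0.40 with an estimated correlation; fry adjusted p = 0.021). Cldn6, a tight junction gene, fell from 291 CPM ± 17.2 (SD, n = 2) to 123 CPM ± 2.1 (SD, n = 2), a log2 fold change of -1.22 (SE 0.10, adjusted p = 4.9e-05). Eomes, a transcription factor of the trophoblast lineage, fell from 127 CPM ± 0.95 (SD, n = 2) to 43.9 CPM ± 15.9 (SD, n = 2), a log2 fold change of -1.52 (SE 0.20, adjusted p = 0.00089). Dppa1 and Lrp2 fell by 0.55 (SE 0.07, adjusted p = 0.00083) and 0.31 (SE 0.04, adjusted p = 0.0016). Of 10 inner cell mass genes, 4 rose, 1 fell and 5 did not pass (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.090). The pluripotency genes Fbxo15, Esrrb and Nanog rose by 0.31, 0.61 and 0.36 (adjusted p = 0.0025, 0.0035 and 0.020), whereas Sox2 fell by 1.75 (SE 0.30, adjusted p = 0.0043). In the primitive endoderm list, the laminin genes Lama1 and Lamb1 fell by 2.14 (adjusted p = 0.015) and 0.59 (adjusted p = 0.035) and the other 8 did not pass the test.

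Part of the stress-response genes were higher in Eed matKO. In the integrated stress response list, 7 of 14 members rose, 2 fell and 5 did not pass the test in edgeR (9 rose and 2 fell adjusted over the list alone; median log2 fold change 0.61, camera adjusted p = 0.0045; adjusted p = 0.55 with an estimated correlation). Asns, asparagine synthetase, rose from 79.6 CPM ± 9.3 (SD, n = 2) to 149 CPM ± 13.4 (SD, n = 2), a log2 fold change of 0.92 (SE 0.13, adjusted p = 0.0015). Psat1, a serine synthesis gene, rose by 0.52 (adjusted p = 0.0019) and Ddit4 by 1.37 (adjusted p = 0.0023), whereas the lipoprotein receptor gene Vldlr fell by 2.61 (adjusted p = 0.0044). Of 16 p53 target genes, 4 rose and 12 did not pass (6 rose adjusted over the list alone; median 0.20, camera adjusted p = 0.023; adjusted p = 0.40 with an estimated correlation). They were Cdkn1a, Pmaip1, Mdm2 and Eda2r, with log2 fold changes of 0.41, 0.68, 0.36 and 0.55 and adjusted p between 0.020 and 0.039.

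Other lists held few or no changed genes in Eed matKO. Ribosomal protein genes had a median log2 fold change of 0.13 with none of 24 members past the test (camera adjusted p = 0.023; adjusted p = 0.67 with an estimated correlation). Tet1 and Dnmt3b, of the DNA methylation machinery, fell by 0.37 (edgeR adjusted p = 0.014) and 0.54 (adjusted p = 0.038), and 11 of 13 members did not pass. In the FGF-ERK list the immediate early gene Fos rose by 1.92 (adjusted p = 0.0016) and Dusp6 fell by 1.36 (adjusted p = 0.0086). The hexokinase gene Hk1 rose by 1.16 (adjusted p = 0.0031) among 13 glycolysis genes with a median of -0.32, and Sdha fell by 0.25 (adjusted p = 0.017) among 21 genes of oxidative phosphorylation with a median of 0.01. No member passed the test among PRC2 genes (median 0.06), PRC1 genes (0.12), developmental regulators (-0.35), modifiers of H3K27 and H3K9 (0.17), cell cycle genes (0.10), genes of zygotic genome activation (0.12) and oocyte genes (0.24). Of 8 genes that escape X inactivation 2 rose in summed counts (median 0.18), and 1 of 3 members of the imprinted X cluster, 1600014K23Rik, fell (-1.81, adjusted p = 0.0079). The summed counts of 9 cumulus cell genes were 242 CPM ± 0.74 (SD, n = 2) in Eed CTR and 247 CPM ± 30.8 (SD, n = 2) in Eed matKO. Most of these came from Nr5a2, which embryos express too, and the means without it were 12.9 and 7.65 CPM. Those of 8 sperm genes were 339 CPM ± 12.8 (SD, n = 2) and 306 CPM ± 12.2 (SD, n = 2). Of the sperm gene counts, 51.0% ± 7.2 (SD, n = 2) and 55.8% ± 7.3 (SD, n = 2) were maternal, so that they do not measure sperm RNA. All 48 Y-linked genes of the table had 0 counts.

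The count of 851 genes depended on the libraries of the Eed set. It was 444, 372, 492 and 484 without Eed CTR replicate 1, Eed CTR replicate 2, Eed matKO replicate 1 and Eed matKO replicate 2, and 327 with DESeq2.

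The second comparison asked what changed when maternal EED and maternal Xist were lost together. In Eed/Xist matDKO, 6 of 289 X-linked genes rose in maternal counts, 2 of 6 core and 5 of 14 preimplantation members of the noncanonical imprinted genes rose in maternal counts, and few summed counts changed. Of 9224 genes, 12 rose and 3 fell (edgeR, adjusted p under 0.05), and 1 of the 15, Tsix, was X-linked. The fit shares 1 estimate of the spread, but replicates differed more in the Eed set. Their chi-square per degree of freedom was 1.54 and 1.65 there, against 1.16 and 1.33 in the Eed/Xist set. Fitted to 1 set alone, Eed/Xist matDKO had 35 genes and Eed matKO 489, so that the gap between 15 and 851 depends partly on this sharing. Lincenc1 rose from 21.5 CPM ± 21.5 (SD, n = 2) to 347 CPM ± 11.2 (SD, n = 2), a log2 fold change of 4.01 (SE 0.33, adjusted p = 0.00010). Cox7b2, which encodes a cytochrome c oxidase subunit, rose from 40.3 CPM ± 3.8 (SD, n = 2) to 193 CPM ± 4.3 (SD, n = 2), a log2 fold change of 2.26 (SE 0.16, adjusted p = 3.8e-05), and 9.97% ± 8.2 (SD, n = 2) of its counts in Eed/Xist matDKO were maternal. Fos rose by 1.85 (SE 0.27, adjusted p = 0.026) and Nat2 by 1.57 (SE 0.24, adjusted p = 0.028). Glrb, Bbx, Prl3b1, Prmt1, Sfmbt2, Tnfsf13b and Gab1 rose by 0.91, 0.82, 0.82, 0.73, 0.59, 0.55 and 0.39, with adjusted p between 0.0185 and 0.049. Laptm5, Golm1 and the desmosome gene Dsg2 fell by 1.43, 0.99 and 0.40, with adjusted p of 0.044, 0.044 and 0.049. The count of 15 was 3 without either Eed/Xist CTR replicate or without Eed/Xist matDKO replicate 1, 5 without Eed/Xist matDKO replicate 2, 26 and 31 without Eed matKO replicates 1 and 2, and 7 with DESeq2.

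Maternal X-linked genes had a median log2 fold change of 0.05 in Eed/Xist matDKO (289 genes; 6 rose, none fell and 283 did not pass the test in edgeR; 11 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.28). At an unadjusted p under 0.05, 655 of all 8090 genes tested on maternal counts differed, and 30 passed the adjusted test. The X share of maternal counts was 3.67% ± 0.07 (SD, n = 2) in Eed/Xist CTR and 3.77% ± 0.05 (SD, n = 2) in Eed/Xist matDKO. Paternal X-linked genes had a median of 0.00 (183 genes, none past the test; camera adjusted p = 0.83), and over both alleles the median was -0.01 (306 genes; camera adjusted p = 0.98). The paternal median was -0.52 without Eed/Xist matDKO replicate 1 (adjusted p = 2.9e-05) and 0.36 without Eed/Xist matDKO replicate 2 (adjusted p = 2.2e-05), so that its sign depended on the library left out. The list of the X-inactivation centre had a median of 0.84 on summed counts (1 of 7 rose, 3 adjusted over the list alone; camera adjusted p = 0.00022; adjusted p = 0.40 with an estimated correlation; fry adjusted p = 0.022). On maternal counts Tsix rose by 3.23 (SE 0.25, adjusted p = 8.6e-07) and Ftx by 2.16 (adjusted p = 0.011), and Jpx had a value of 3.07 (adjusted p = 0.13).

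Part of the noncanonical imprinted genes gained maternal expression in Eed/Xist matDKO too. The maternal share of the core list was 26.5% ± 2.8 (SD, n = 2) in Eed/Xist CTR and 49.8% ± 0.95 (SD, n = 2) in Eed/Xist matDKO. Paternal counts of that list had a median log2 fold change of -0.29. Maternal counts of 2 of its 6 members rose and none fell in edgeR (4 rose adjusted over the list alone; median log2 fold change 1.08, camera adjusted p = 1.3e-09; adjusted p = 0.081 with an estimated correlation; fry adjusted p = 0.0030). The maternal share of Sfmbt2 was 1.54% ± 1.4 (SD, n = 2) in Eed/Xist CTR and 44.1% ± 4.9 (SD, n = 2) in Eed/Xist matDKO (log2 allelic change 5.75, SE 0.43, adjusted p = 1.0e-08). That of Gab1 was 28.7% ± 3.5 (SD, n = 2) and 53.1% ± 4.5 (SD, n = 2) (1.64, SE 0.18, adjusted p = 4.7e-06), and that of Bbx was 8.45% ± 4.7 (SD, n = 2) and 42.2% ± 4.1 (SD, n = 2) (3.08, SE 0.28, adjusted p = 3.3e-07). Slc38a4 went from 0.735% ± 1.0 (SD, n = 2) to 21.0% ± 11.8 (SD, n = 2) (adjusted p = 0.0095). Of 14 members of the preimplantation list, maternal counts of 5 rose and none fell (10 rose and 1 fell adjusted over the list alone; median 1.36, camera adjusted p = 3.5e-14; adjusted p = 0.081 with an estimated correlation). The 7 members of both lists that rose became 4 without Eed/Xist CTR replicate 1, 3 without Eed/Xist CTR replicate 2, 4 without Eed/Xist matDKO replicate 1 and 4 without Eed/Xist matDKO replicate 2, and 4 with DESeq2 or with a replicate block. They included Fam198b (1.29, adjusted p = 0.0026) and Gramd1b (2.57, adjusted p = 0.034). Platr4 passed as well (0.87, adjusted p = 0.032), but its allelic share hardly moved, with 149 of 155 counts maternal in Eed/Xist CTR and 259 of 271 in Eed/Xist matDKO. Canonical imprinted genes had no member past the test among 19 on summed counts, where 922 of 9224 genes had an unadjusted p under 0.05, and DESeq2 gave 0 as well.

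Trophectoderm genes had a median log2 fold change of -0.13 in Eed/Xist matDKO, with none of 23 past the edgeR test (1 fell adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.43 with an estimated correlation). The p53 target genes had a median of 0.18 with none of 16 past the test (5 rose adjusted over the list alone; camera adjusted p = 0.0045; adjusted p = 0.40 with an estimated correlation). The integrated stress response list had a median of 0.13 (3 of 14 rose adjusted over the list alone; camera adjusted p = 0.053).

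The third comparison tested whether the effect differed between the knockouts, each set against its own controls. On maternal counts the X-linked median of the difference was 0.62 (34 of 289 higher and 255 not past the test; 91 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.8e-26; adjusted p = 0.081 with an estimated correlation), and on paternal counts it was -1.09 (none of 183 past the edgeR test, where 690 of 7711 genes had an unadjusted p under 0.05; 15 lower adjusted over the list alone; camera adjusted p = 8.1e-23; adjusted p = 0.466 with an estimated correlation). On summed counts 45 of 9224 genes differed, 31 with a higher and 14 with a lower effect in Eed/Xist matDKO, and 13 of the 31 were X-linked. Msn had an effect of -3.48 in Eed matKO and a difference of 3.82 (SE 0.40, edgeR adjusted p = 0.0011), and Firre, an X-linked noncoding RNA, had a difference of 3.13 (SE 0.58, adjusted p = 0.045). Rlim, C430049B03Rik and Hmgn5 differed by 1.64, 2.90 and 1.87 (adjusted p = 0.0010, 0.0010 and 0.0011). The autosomal kinase gene Ptk2b differed by 2.98 (SE 0.58, adjusted p = 0.048) and the phosphodiesterase gene Pde8a by 2.73 (SE 0.51, adjusted p = 0.045). Kng2, Irak3, EU599041, Kng1 and Derl3 rose more in Eed matKO, with differences of -2.84, -2.19, -2.03, -1.61 and -1.58 and adjusted p between 0.011 and 0.045. Over both alleles the X-linked median of the difference was 0.07 (306 genes; camera adjusted p = 0.0504), and it depended on the library left out. It passed the threshold without Eed CTR replicate 2 (0.08, adjusted p = 0.018), Eed matKO replicate 1 (0.25, adjusted p = 0.00024), Eed/Xist CTR replicate 2 (0.14, adjusted p = 0.0079) and Eed/Xist matDKO replicate 2 (0.16, adjusted p = 0.0011), and it was below 0 without Eed matKO replicate 2 (-0.0228, adjusted p = 0.48) and Eed/Xist matDKO replicate 1 (-0.0076, adjusted p = 0.40). Glycolysis genes had a median difference of 0.41 (camera adjusted p = 0.039, or 0.43 with an estimated correlation) with no member past the test. Their counts together were 1061 CPM in Eed matKO and 1098 CPM in Eed/Xist matDKO, against 1194 CPM in Eed CTR and 1045 CPM in Eed/Xist CTR. The gap between the controls is thus part of this difference. Of the trophectoderm genes, 1 of 23 differed, Cldn6 (1.04, SE 0.14, edgeR adjusted p = 0.0086). The list's median was 0.20 (5 higher adjusted over the list alone, camera adjusted p = 0.031, or 0.43 with an estimated correlation). Its counts together were 5551 CPM in Eed matKO and 5707 CPM in Eed/Xist matDKO, against 6736 CPM in Eed CTR and 6242 CPM in Eed/Xist CTR, so that the controls differed here too. On maternal counts none of the 6 noncanonical core genes passed the edgeR test, where 890 of 8090 genes had an unadjusted p under 0.05. Their median difference was -0.31, from -1.56 for Slc38a4 (SE 1.90) to 0.02 for Jade1 (SE 0.20). On drawn counts the test recovered 41.0% of 2-fold differences. That rate is over tested genes drawn at 1 common dispersion, so that it does not measure the power for a single gene such as Slc38a4. The count of 45 fell to 12 without Eed CTR replicate 2, to 9 and 21 without Eed/Xist CTR replicates 1 and 2, to 18 and 14 without Eed/Xist matDKO replicates 1 and 2, and to 22 with limma-voom. The paternal X-linked difference was -1.73 without Eed CTR replicate 1 and -0.69 without Eed CTR replicate 2.

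Genes outside the X chromosome that changed in Eed matKO mostly had an effect of the same sign in Eed/Xist matDKO, as 611 of 784 (77.9%) did. The effects there were smaller, with a slope of 0.20 on those in Eed matKO. These genes were picked for their change in Eed matKO, which by itself lowers the slope. Both knockouts called 8 genes higher, where independent lists would share 0.511, and 3 genes lower, where they would share 0.149, and no gene was called in opposite directions. This overlap rests on few calls in Eed/Xist matDKO. With a replicate block 5 genes were called higher and 0 lower there, so that fewer could be shared. Across all 9224 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson correlation of 0.28 and a Spearman correlation of 0.26. The comparisons share no control library, but they share the estimate of the spread. Allelic ratios of 11 genes, all outside the X chromosome, moved toward the maternal allele in both knockouts. With library-size scaling fewer genes than that changed in Eed/Xist matDKO, so that the shared count would be lower.

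**Figure D4:**
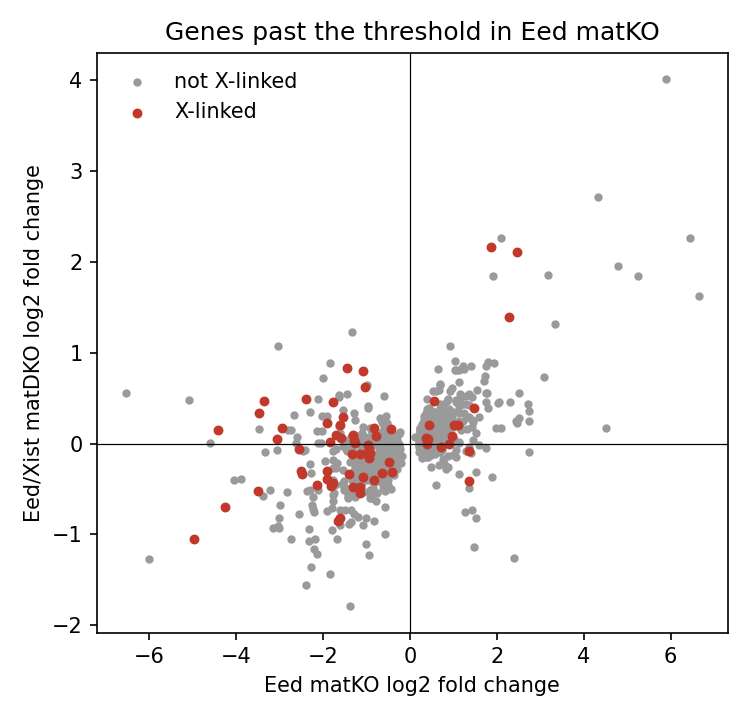
Fitted log2 fold change in Eed matKO (horizontal) and in Eed/Xist matDKO (vertical) for the 851 genes past the threshold in Eed matKO, 67 of them X-linked. Of the 784 genes off the X chromosome, 611 have the same sign on both axes; values of genes with a group at 0 counts depend on the prior count of the fit.

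The control groups were compared as a background, since the sets differ in mouse line and pool size. Of 9224 genes, 3 differed between Eed/Xist CTR and Eed CTR in edgeR on summed counts, and 16 of 8090 differed on maternal counts and 8 of 8631 in allelic ratio. Zfp626, a zinc finger gene, was higher by 1.04 (SE 0.14, adjusted p = 0.028), and Klhl30 was lower by 2.74 (SE 0.25, adjusted p = 0.00089). Chit1, a chitinase gene, had 133 counts in Eed/Xist CTR against 1 in Eed CTR, a ratio of 121 (95% exact interval 21.3 to 4803), and 57.6 CPM ± 10.4 (SD, n = 2) in Eed/Xist matDKO. Glycolysis genes had a median of -0.33 (13 genes; camera adjusted p = 0.023; adjusted p = 0.40 with an estimated correlation), integrated stress response genes one of 0.30 (14 genes; adjusted p = 0.0080; adjusted p = 0.55 with an estimated correlation) and trophectoderm genes one of -0.10 (23 genes; adjusted p = 0.031; adjusted p = 0.43 with an estimated correlation), with no member of these lists past the test. Paternal X-linked genes had a median of 0.24 (183 genes; camera adjusted p = 0.017; adjusted p = 0.79 with an estimated correlation), maternal ones one of -0.11 (289 genes; adjusted p = 0.0049; adjusted p = 0.63 with an estimated correlation) and their allelic ratios one of -0.38 (280 genes; adjusted p = 8.7e-05; adjusted p = 0.71 with an estimated correlation). The count of 3 was 32 and 38 without Eed matKO replicates 1 and 2, and 1 without Eed/Xist CTR replicate 1.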

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

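All tests of possible causes in this part were chosen only after the results were seen. The values below drew attention because the 2 knockouts differed in them.

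In paternal counts, X-linked genes differed between the knockouts by a median of -1.09 and genes that escape X inactivation by -0.88 (camera adjusted p = 8.1e-23 and 0.025; adjusted p = 0.466 for each list with an estimated correlation). The X-linked median was 1.09 in Eed matKO and 0.00 in Eed/Xist matDKO, where it was -0.52 and 0.36 without Eed/Xist matDKO replicates 1 and 2. A larger part of female embryos in the Eed matKO pools could raise paternal X-linked counts. Paternal Xist would then rise too, if its level per female embryo were unchanged. It had a log2 fold change of -0.0580 (SE 0.26), 4.47 SE below the X-linked median. That SE is of Xist alone and leaves out the error of the median, which ran from 0.75 to 1.69 with 1 library left out. The Xist level per female embryo was not measured and the sex of the embryos is unknown. The value thus argues against more female embryos as the whole cause only under that condition. Scaling, which cannot move a share within a library, is excluded by the X share of paternal counts, which was 2.04 times that of the controls on average, with a lowest value of 1.72% in Eed matKO and a highest of 1.20% in Eed CTR. Loss of maternal EED could raise paternal X-linked expression through maternal Xist, but the difference between the knockouts, at an adjusted p of 0.466 with an estimated correlation, leaves this open.

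Maternal Xist had a difference of -1.91 between the knockouts, yet Xist counts from the maternal allele remained in Eed/Xist matDKO. Their share of Xist counts was 25.6% (exact 95% interval 22.8 to 28.6) in replicate 1 and 51.6% (47.5 to 55.6) in replicate 2. In Eed/Xist CTR it was 46.2% (42.5 to 49.9) and 41.8% (38.4 to 45.3), so that these shares lay on either side of the controls. The maternal Xist counts themselves were lower in both replicates, at 229 and 310 against 333 and 341 in Eed/Xist CTR. Paternal Xist counts were 666 and 291 against 388 and 475. A deletion that failed in all embryos could leave maternal Xist counts, but maternal X-linked genes should then have fallen as in Eed matKO. Their median was 0.0472, which argues against this if the Eed/Xist line responds as the Eed line does. A deletion missed in part of the 13 pooled embryos of a library was not tested and could leave these counts too. Antisense transcripts counted as Xist could also leave them, and maternal Tsix rose by 3.23, but without strand and without the deleted part being stated this stays open.

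The autosomal maternal share was 52.2% ± 0.16 (SD, n = 2) in Eed CTR and 57.0% ± 2.8 (SD, n = 2) in Eed matKO, where replicate 2 alone had 54.98%, against 54.2% ± 1.1 (SD, n = 2) in Eed/Xist CTR and 51.9% ± 0.61 (SD, n = 2) in Eed/Xist matDKO, and the shares were not tested as such. Maternal cumulus cells could raise it if they gave 10.1% of the counts of Eed matKO (5.90% from replicate 2 alone). Of 16 cumulus genes other than Nr5a2, which embryos express too, 8 had no count in any library and cannot be read, and the other 8 had 6 maternal counts in Eed matKO against 17 in its controls. The upper exact 95% limit of those 6 counts is 112 per 1e6 of the 116390 counts needed at the lower share, under a least value of 1000 per 1e6 for cumulus cells, which argues against them, but that bound was assumed without a cumulus profile and set after these counts were seen, once a ratio of cumulus counts to the controls (0.592) had decided nothing. Oocyte RNA that persisted could raise the share too, and oocyte genes had a maternal median of 0.16 (7 genes, camera adjusted p = 0.48), which leaves it open.

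The effect differed in 45 genes on summed counts, in 66 genes on maternal counts and in 11 genes on allelic ratios. The 11 were 43 and 5 without Eed CTR replicates 1 and 2, 17 without Eed matKO replicate 1, 2 without Eed/Xist CTR replicate 2, and 26 and 7 without Eed/Xist matDKO replicates 1 and 2, and library-size scaling gave 5 higher and 5 lower in place of 10 and 1. The 45 ranged from 9 to 38 with 1 library left out, and the 66 were not counted again. Lists passed camera at the preset correlation, and none of them did with an estimated one, whose adjusted p is given with each median. Maternal X-linked genes had a median difference of 0.62 (adjusted p = 0.081) and their allelic ratios one of 1.74 (0.61). The X-inactivation centre had medians of 0.97 on summed counts (0.40) and 1.54 on maternal counts (0.15). Glycolysis genes differed by a median of 0.41 (0.43) and trophectoderm genes by 0.20 (0.43), and for both lists a gap between the control groups is part of the difference. Among called genes with an average log2 CPM of 3 or more and without a provisional symbol, Msn, Firre, Ptk2b, Tsix and Pde8a had the highest differences, at 3.82, 3.13, 2.98, 2.86 and 2.73. Kng2, Irak3, EU599041, Kng1 and Derl3 had the lowest, at -2.84, -2.19, -2.03, -1.61 and -1.58.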

How the results depend on the processing

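The alternatives for summed counts were planned before the counts were seen, while those for maternal counts, paternal counts and allelic ratios were chosen only after. Limits were 2 libraries per group, embryos pooled by 5 in one set and 13 in the other, allele-assigned reads only, no reciprocal cross and unknown sex of the embryos. The replicate numbers do not pair libraries, with correlations of replicate deviations of 0.010 and -0.032, and replicates differed beyond sampling, with chi-square per degree of freedom from 1.16 to 1.65 on summed, 1.27 to 1.69 on maternal and 1.29 to 1.67 on paternal counts. The Y-linked covariate was not run. The cause of the shifts below was not tested.

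With DESeq2, the 851 genes of Eed matKO became 327, the 15 of Eed/Xist matDKO 7, the noncanonical genes of Eed/Xist matDKO went from 3 to 1 and on maternal counts from 7 to 4. With limma-voom the 45 genes of the difference became 22 and the 3 of the controls 1. With DESeq2 size factors the controls gave 8 genes and the summed X-linked difference, 0.0680, had an adjusted p of 0.048. Without a filter the counts were 1314, 160, 302 and 248, and for noncanonical genes 7 in each knockout and 12 on maternal counts in Eed/Xist matDKO. With the strict filter canonical genes in Eed matKO went from 2 to 1.

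In a fit to 1 set, Eed matKO gave 489 genes, Eed/Xist matDKO 35, noncanonical genes 5 in Eed/Xist matDKO, and 6 in place of 10 on maternal counts in Eed matKO. With a replicate block, Eed matKO gave 713, Eed/Xist matDKO 5, the difference 17, noncanonical genes in Eed/Xist matDKO 0 and on maternal counts 4. At an adjusted p under 0.01 the counts were 268, 3, 9 and 1, and noncanonical genes 2 and 0. With an added log2 fold change of 1 they were 301 and 6 genes, and noncanonical genes 2 and 0. With library-size scaling, allelic changes in Eed/Xist matDKO went from 14 to 9. Those in Eed matKO went from 38 toward maternal and 74 toward paternal to 71 and 42 (80 shared genes), and those of the difference from 10 and 1 to 5 and 5 (6 shared genes).

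Leaving out each library in turn, counts ranged from 372 to 760 (Eed matKO), 3 to 31 (Eed/Xist matDKO), 9 to 38 (difference) and 1 to 38 (controls). Noncanonical genes ranged from 2 to 4 and 0 to 4, on maternal counts from 6 to 10 and 3 to 7, and canonical genes in Eed matKO from 1 to 3. Allelic changes ranged from 40 to 116, 6 to 17 and 2 to 43. Xist had log2 fold changes of 0.55 to 0.89 in Eed matKO and -0.32 to 0.19 in Eed/Xist matDKO. X-linked medians ranged on summed counts from -0.26 to -0.0251, -0.10 to 0.04 and -0.0228 to 0.25, on maternal counts from -0.72 to -0.52, 0.02 to 0.07 and 0.58 to 0.74, and on paternal counts from 0.75 to 1.69, -0.52 to 0.36 and -1.73 to -0.69 (Eed matKO, Eed/Xist matDKO, difference). The paternal value of Eed/Xist matDKO was reversed, at 0.36, without Eed/Xist matDKO replicate 2.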

Other observations

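The test of paternally biased genes in this part was chosen only after the results were seen. Several genes outside the imprinting lists had a higher maternal share of counts in both knockouts. Bend4, of the BEN domain family, had a maternal share of 5.55% ± 1.8 (SD, n = 2) in Eed CTR and 37.5% ± 12.0 (SD, n = 2) in Eed matKO, and 7.04% ± 3.8 (SD, n = 2) in Eed/Xist CTR and 41.8% ± 5.0 (SD, n = 2) in Eed/Xist matDKO (edgeR adjusted p = 0.0020 and 0.00018). Tbx18, a T-box transcription factor gene, went from 5.81% ± 1.6 (SD, n = 2) to 47.1% ± 0.67 (SD, n = 2) and from 2.50% ± 0.088 (SD, n = 2) to 26.6% ± 3.5 (SD, n = 2). Aim2, a DNA sensor gene, went from 4.55% ± 6.4 (SD, n = 2) to 41.9% ± 1.9 (SD, n = 2), and from 0 of 50 counts to 50.4% ± 9.9 (SD, n = 2). Summed counts in Eed CTR and Eed matKO were 205 and 105 for Bend4, 86 and 72 for Tbx18, and 53 and 69 for Aim2. For Bend4 and Tbx18, fewer paternal counts were thus part of the higher share in Eed matKO. In Eed/Xist CTR and Eed/Xist matDKO the sums were 205 and 230, 80 and 84, and 50 and 114.

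Genes with a weaker paternal bias in the controls, or none, also shifted toward the maternal allele. Pla2g7, which encodes a lipoprotein-associated phospholipase, went from 30.3% ± 6.4 (SD, n = 2) to 94.2% ± 2.5 (SD, n = 2) and from 55.2% ± 6.4 (SD, n = 2) to 85.1% ± 0.33 (SD, n = 2). Sfxn1, a mitochondrial serine transporter gene, went from 37.5% ± 4.5 (SD, n = 2) to 73.3% ± 5.2 (SD, n = 2) and from 47.2% ± 3.2 (SD, n = 2) to 70.8% ± 3.9 (SD, n = 2). Plod2, a collagen-modifying enzyme gene, had log2 allelic changes of 0.98 and 1.06 (edgeR adjusted p = 0.027 and 0.022).

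Loss of maternal EED might raise the maternal share of genes with paternal bias more widely, but few single genes passed the test. Genes with a maternal share of 20% or less in the Eed controls and in no imprinting list had a median allelic log2 change of 0.17 in Eed/Xist matDKO (195 genes, 119 toward maternal), above 99.99% of 10000 random lists of the same counts. The 3 past the edgeR test were Aim2, Bend4 and Tbx18, and the other 192 had a median of 0.16, above 99.99% of as many random lists. Genes chosen in the Eed/Xist controls had a median of 0.18 in Eed matKO (173 genes, 97 toward maternal), and 0.16 without the same 3. Of the others, Rfx4 and Mgst2 passed toward maternal and Glrb toward paternal. Genes with maternal bias had a median of 0.00 in both. Random lists were drawn over genes of the same libraries and matched on total counts, not on allelic share. Their percentiles treat genes as independent and do not measure the spread between libraries. These libraries hold no reciprocal cross, so that bias by strain cannot be told from bias by parent. Reads from morulae of the reverse cross, counted by allele over these genes, could separate the 2.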
